A study of Mus musculus with 18 samples.

How the data were processed

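RNA-seq libraries of dentate gyrus were grouped by their sample titles into EYFP_OE, cFos_OE, shRNA-Ctrl_E0, shRNA-Ctrl_E1, shRNA-cFos_E0 and shRNA-cFos_E1, with 3 libraries each. The labels' protocols state that a library was made from each individual mouse. Per the submitters' processing notes, TopHat2 and DESeq2 were used with the genome build mm9, and no versions are given there. The counting tool, the annotation, the strand setting and the delivery of the constructs are not given in the sources used here. With the strand setting unknown, counts of overlapping and antisense genes are taken as deposited. No coordinates are printed, since the annotation at hand is for a later mouse build than mm9.

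The 3 tables hold the authors' own comparisons, E1 against E0 with shRNA-Ctrl, E1 against E0 with shRNA-cFos, and c-Fos overexpression against EYFP, with 24015 rows each. Per the file headers, each deposited row gives the mean normalized count over the libraries of the comparison, a signal value on the scale of counts divided by size factors. Per the file headers, the authors' DESeq2 fit also gives a log2 fold change and its standard error on the log2 scale. The deposited Wald score equals the log2 fold change over its standard error, as checked on every row. The deposited p-value is the 2-sided normal p of that score, and the adjusted p-value is the Benjamini-Hochberg value over genes above a minimum mean normalized count. The smallest mean count with an adjusted p was 5.40 for shRNA-Ctrl, 12.2 for shRNA-cFos and 3.64 for overexpression. The tables contain 0 columns of values per library, so no library was tested, averaged or left out here, and the depth of each library is unknown. Precision is therefore that of the authors' standard errors, whose median over tested genes was 0.11 for shRNA-Ctrl, 0.12 for shRNA-cFos and 0.12 for overexpression. The sign of the shRNA tables follows the naming of the comparison, E1 over the sham state, and that of overexpression follows Fos.

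The values show that the authors' log2 fold changes were shrunken toward 0. Standard errors fall again among genes with the lowest means, and reach at most 0.29, 0.26 and 0.20, as a zero-centred normal prior of standard deviation 0.59, 0.53 and 0.41 gives in the 3 tables. As an alternative chosen after seeing the data, the prior was removed algebraically from each deposited log2 fold change and standard error. For genes with little information this step has 2 solutions and takes the one with the smaller standard error, so such values are uncertain. Fos with overexpression is among them, as are several interferon response genes in the shRNA tables, and levels set across tables inherit this.

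In the table for overexpression, 27 gene names had been turned into dates, as spreadsheet programs do, and these rows were left out. An adjusted p listed as 0 is below the smallest number the authors' software could write. Genes with a fold change and no p, which DESeq2 gives for a count far from the others, numbered 10, 2 and 9 in the deposited tables and were not counted as tested.

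The plan, written before the data were examined, was to fit counts or normalized values per library. For the case of comparisons alone it named the steps taken here. Genes were called at the authors' adjusted p under 0.05. The difference of the E1 responses was tested as the difference of the 2 log2 fold changes over the root of the summed squared standard errors, with a 2-sided normal p and Benjamini-Hochberg adjustment over the 14386 genes tested in both tables. The direct comparisons of shRNA-cFos with shRNA-Ctrl at E0 and at E1 were not run, because the arms were normalized separately. Levels set across the shRNA tables were computed from the mean normalized count and the unshrunken fold change of genes with a mean of at least 50 in both, after shifting by the median log2 ratio of the E0 levels over 12406 genes (-0.43). They carry no error.

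Gene lists of 26 pathways and cell types were fixed before the data were examined, and 4 lists were added afterwards and hold genes already seen to change. For each list the members past the threshold were counted over all genes and adjusted over the list alone. The median log2 fold change was placed among those of 10000 random lists of the same size matched on mean count in 20 bins, for lists with at least 5 tested members. No set test with a correlation between genes could be run. Mitochondrially encoded genes have 0 tested members in these tables.

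Named genes followed a rule set in advance: per comparison, the 10 higher and 10 lower genes with the smallest adjusted p, passing over model names, with Fos always and up to 4 members of each list with the largest changes. List members outside that rule, such as the immediate early genes listed in full, were chosen after their values were seen. Agreement between tables was measured by Spearman correlations across genes, by shared calls beside the overlap of independent lists, and by Fisher's exact test.

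The difference test was tested on simulated data for the 14386 genes, with 50 genes changed at each of 4 sizes. It recovered 32% of simulated log2 differences of 0.5, 62% of 1, 96% of 2 and 100% of 4, and 7 unchanged genes were called. Only 200 genes were changed and errors were drawn independently from the deposited standard errors. The shares recovered and the false calls may therefore differ in the real data, where far more genes were called. Alternatives were adjusted p thresholds of 0.01 and 0.1, a fold minimum of 1.5, no filter on the mean count, a minimum 5 times as high, subsets of genes for the correlations, lists without shared members, and the removal of the prior. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9.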

Results

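RNA was sequenced from the dentate gyrus, the hippocampal field whose main cells are granule neurons, of C57BL/6 mice aged 8 weeks. The 18 libraries formed 6 groups of 3, and per the labels' protocols each library came from its own animal. The groups EYFP_OE and cFos_OE overexpressed a yellow fluorescent protein or c-Fos, a subunit of the AP-1 transcription factor that neurons make within minutes of activity. The other 4 groups carried a short hairpin RNA, either a control (shRNA-Ctrl) or one named for c-Fos (shRNA-cFos), and were taken at E0 or E1. The series is described as a study of gene expression and chromatin after neuronal activation, and the deposited comparisons set E1 against a sham state. The values used were the authors' 3 tables of fold changes, so the depth of each library is unknown. Mean normalized counts in the authors' deposited tables had a median over tested genes of 420 for the shRNA-Ctrl comparison, 374 for shRNA-cFos and 325 for overexpression. Each log2 fold change below is given ± its standard error where one is printed.

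Fos, the targeted gene, rose at E1 in both shRNA arms and with overexpression. In the authors' deposited table for shRNA-Ctrl its log2 fold change was 3.36 ± 0.14, and in the authors' deposited table for shRNA-cFos it was 2.33 ± 0.15. The E1 response of Fos was thus smaller with shRNA-cFos, by a log2 difference of -1.03 ± 0.20 computed from the authors' deposited tables (normal approximation, Benjamini-Hochberg adjusted p = 1.1e-05). With c-Fos overexpression Fos stood at 3.34 ± 0.20 in the authors' deposited table, a value pulled toward 0 by the fitting (6.02 with the prior removed, an uncertain value). Levels estimated from the authors' deposited tables, after scaling the separately normalized shRNA tables to each other, put Fos at E0 at 178 normalized counts with shRNA-Ctrl and 230 with shRNA-cFos. At E1 the same estimate from the authors' deposited tables gave 2126 and 1348. These levels carry no error and no test. The log2 ratio of shRNA-cFos to shRNA-Ctrl at E0 was 0.37 with the scaling and -0.06 without it, from the authors' deposited tables. Without scaling, E0 levels in the shRNA-cFos table lay lower for genes at large (median log2 ratio -0.43 over 12406 genes). The total of mean normalized counts was lower in that table too. The unscaled ratio carries this offset between the tables, so it is no sign of less Fos at E0 with shRNA-cFos.

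The first comparison asked which genes followed neuronal activation with the control hairpin. Immediate early transcription factors, the first genes that neurons switch on after activity, rose strongly at E1, led in the authors' deposited table by Fosb (5.83 ± 0.12), Atf3 (32.0-fold), Egr3 (4.06 ± 0.10) and Nr4a2 (4.03 ± 0.14). Of the 24 members of this list, 20 rose and 2 fell in the authors' deposited table, with a median of 2.57 (21 and 2 adjusted over the list alone). The 2 that fell were Klf2 (-0.89) and Klf4 (-0.70) in the authors' deposited table. Activity-induced effectors, which act at synapses and in signalling, rose for 27 of 28 members in the authors' deposited table, with a median of 2.39 (27 higher and 1 lower adjusted over the list alone). Among them, Nptx2, a pentraxin that clusters AMPA receptors, had a log2 fold change of 4.65 ± 0.12 in the authors' deposited table. Arc, which drives AMPA receptor endocytosis, had a log2 fold change of 4.41 ± 0.23 there.

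Feedback inhibitors of MAP kinase signalling rose for 11 of 14 members and fell for 2 in the authors' deposited table (12 and 2 adjusted over the list alone), with Spry2 at 2.58 ± 0.10 and the phosphatase gene Dusp4 at 2.41 ± 0.11. Heat shock and unfolded protein response genes rose for 18 of 20 members in the authors' deposited table (18 adjusted over the list alone), among them the chaperone gene Hspa5 (1.20 ± 0.06) and the stress factor gene Ddit3 (1.56 ± 0.15). Neuropeptide and secretory genes rose for 11 of 20 members and fell for 3 in the authors' deposited table (11 and 3 adjusted over the list alone), with Vgf at 1.93 ± 0.11 and Scg2 at 1.31 ± 0.08. Interferon response genes rose for 29 of 29 members in the authors' deposited table, with a median of 1.01 (29 adjusted over the list alone) and examples in Ifit1 (1.32 ± 0.29) and Bst2 (1.18 ± 0.28). With the prior removed this median was 1.55, and the standard errors of the list were 3.14 times those of genes of like mean count, computed from the authors' deposited table. Both values are uncertain, since several members have standard errors near the largest found. Microglial markers rose for 10 of 14 members in the authors' deposited table (11 adjusted over the list alone, median 0.34), as did 6 of 12 reactive astrocyte markers (6 adjusted over the list alone, median 0.53). The oligodendrocyte markers had a median of -0.14, with 1 of 12 lower and 0 higher in the authors' deposited table (1 and 0 adjusted over the list alone). Dentate granule neuron markers fell for 10 of 16 members and rose for 2 in the authors' deposited table (10 and 2 adjusted over the list alone, median -0.45), with Tdo2 at -0.96 ± 0.15 and Dsp at -0.84 ± 0.13. Synaptic adhesion and scaffold genes fell for 12 of 31 members and rose for 3 in the authors' deposited table (13 and 3 adjusted over the list alone).

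Other genes with the smallest adjusted p in the shRNA-Ctrl comparison were, in the authors' deposited table, Fosl2 (3.60), Pcdh8 (3.58), Arl4d (3.10), Frmd6 (3.13), Gadd45b (3.73), the kinase gene Plk2 (7.98-fold) and Fam107b (2.25). On the lower side the authors' deposited table listed Islr2 (-1.83), AI593442 (-1.01), Creg2 (-1.08), Ccdc71l (-1.33), Rasl10a (-1.30), Ccdc177 (-1.43), Zfp316 (-1.04), the potassium channel gene Kcnj11 (-1.17), Pm20d2 (-1.36) and Pnmal1 (-0.78). Across all genes, 5173 of 15675 tested passed an adjusted p of 0.05 in the authors' deposited table, 2640 higher and 2533 lower at E1. Changes of at least 2-fold were mostly increases, 328 higher against 99 lower in the authors' deposited table. Without values per library, no animal could be left out and no other split of the animals could be tried. A fold minimum of 1.5 left 1660 genes, 61.4% of them higher, from the authors' deposited table.

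**Figure D1:**
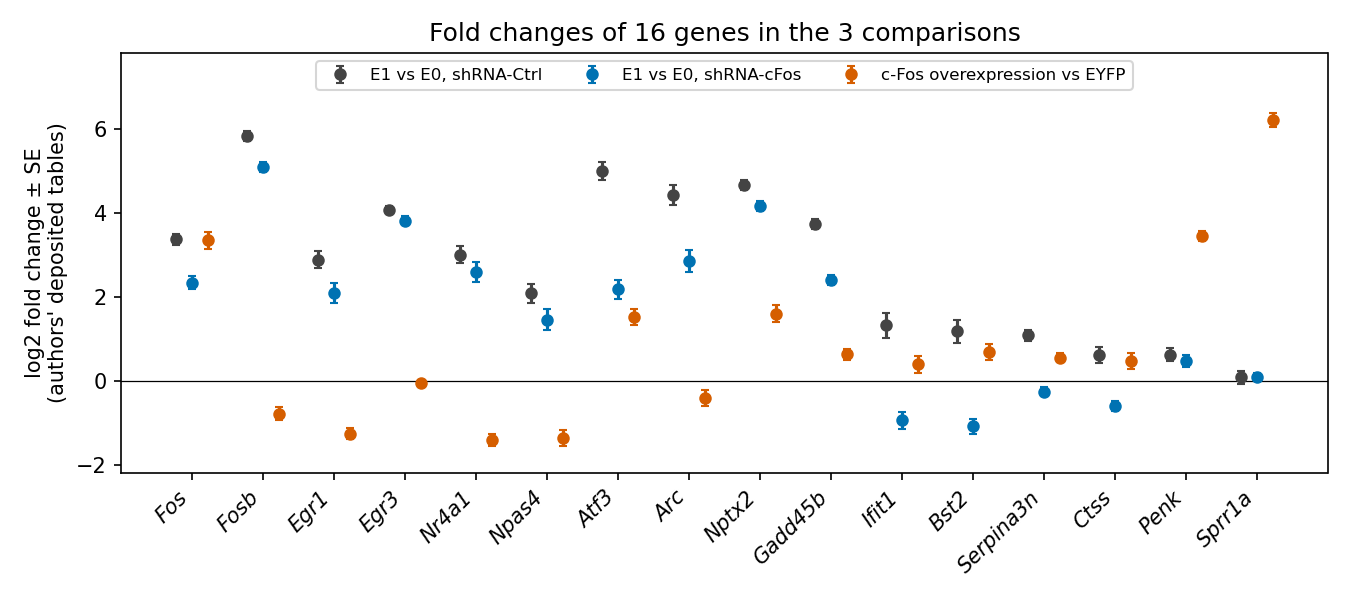
Log2 fold change (vertical axis) of 16 genes chosen after their values were seen, in the authors' deposited tables for E1 against E0 with shRNA-Ctrl, for E1 against E0 with shRNA-cFos and for c-Fos overexpression against EYFP, with bars of 1 standard error. In the authors' deposited tables Fosb lies at 5.83 and 5.09 at E1 and at -0.79 with overexpression, and Ifit1 lies above 0 with shRNA-Ctrl (1.32) and below 0 with shRNA-cFos (-0.95).

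The second comparison took the same step from E0 to E1 in mice with the hairpin named for c-Fos. The activity program rose here too: 20 of 23 immediate early transcription factors were higher and 0 lower in the authors' deposited table, with a median of 2.17 (22 and 0 adjusted over the list alone). Fosb reached 5.09 ± 0.11, Nr4a2 3.81 ± 0.13 and Egr3 3.81 ± 0.11 in the authors' deposited table. Activity-induced effectors rose for 25 of 28 members in the authors' deposited table, with a median of 2.04 (26 adjusted over the list alone), including Nptx2 at 4.15 ± 0.12 and Ptgs2, which encodes cyclooxygenase-2, at 3.51 ± 0.10. Interferon response genes moved the other way, with 23 of 29 lower and 0 higher in the authors' deposited table and a median of -0.78, or -1.06 with the prior removed (26 lower adjusted over the list alone), as in Irf9 (-1.10 ± 0.16) and Bst2 (-1.08 ± 0.18).

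Glial reaction markers fell in this arm, and other cell types did not all follow. Reactive astrocyte markers fell for 7 of 12 members in the authors' deposited table (9 adjusted over the list alone, median -0.55, or -0.70 with the prior removed), among them the intermediate filament gene Gfap (-0.57 ± 0.11). Microglial markers fell for 8 of 14 members and rose for 1 in the authors' deposited table (9 and 1 adjusted over the list alone, median -0.45), as did Ctss (-0.61 ± 0.13). The oligodendrocyte median was -0.15, with 2 of 12 lower in the authors' deposited table (2 adjusted over the list alone). Plain astrocyte markers rose for 7 of 12 members and fell for 1 in the authors' deposited table (7 and 1 adjusted over the list alone). Dentate granule neuron markers rose for 10 of 16 members and none fell in the authors' deposited table (10 higher and 1 lower adjusted over the list alone, median 0.24), led by C1ql3 (0.98 ± 0.09). Synaptic adhesion and scaffold genes rose for 20 of 31 members in the authors' deposited table (20 adjusted over the list alone), with Homer1, itself an activity-induced gene, at 2.86 ± 0.12 and Lrrtm4 at 0.75 ± 0.10. Potassium channel genes rose for 17 of 26 members and fell for 1 in the authors' deposited table (18 and 2 adjusted over the list alone). Glutamate receptor genes rose for 12 of 22 and fell for 1 in the authors' deposited table (14 and 1 adjusted over the list alone). Heat shock and unfolded protein response genes split, with 5 of 20 higher and 5 lower in the authors' deposited table (5 and 6 adjusted over the list alone). MAP kinase feedback genes rose for 9 of 14 members and fell for 1 in the authors' deposited table (9 and 1 adjusted over the list alone), with Dusp4 at 2.56 ± 0.09.

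Further genes with the smallest adjusted p in this arm were, in the authors' deposited table, Pcdh8 (3.53), Fosl2 (2.81), Cenpa (4.66), Arl4d (3.48), Dnajb5 (2.29) and the actin-associated Synpo (2.93). Those that fell were, in the authors' deposited table, Dclk3 (-1.88), the metabotropic glutamate receptor gene Grm2 (-1.02), the ubiquitin ligase gene Fbxo32 (-1.38), Rhobtb2 (-0.73), the cytokine gene Csf1 (-0.94), Rasl10a (-0.83), the proapoptotic Bbc3 (-1.18), Vash1 (-0.64), Islr2 (-0.63) and Gprin1 (-0.55). Calls in the authors' deposited table numbered 4039 of 14388 tested genes, 2349 higher and 1690 lower at E1. At least 2-fold changes numbered 175 higher and 31 lower in the authors' deposited table. With a fold minimum of 1.5 the count fell to 1077, 53.9% of them higher, and at an adjusted p of 0.01 to 2622, 64.7% of them higher, from the authors' deposited table.

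The third comparison asked whether the E1 response itself differed between the hairpins, by testing the difference of the 2 log2 fold changes per gene. Interferon response genes differed most as a group: all 29 had a lower response with shRNA-cFos, with a median difference of -1.75, or -2.72 with the prior removed, computed from the authors' deposited tables (29 adjusted over the list alone). Among single genes, the transcription factor genes Atf3 (-2.83 ± 0.31) and Ddit3 (-2.00 ± 0.20) had a lower response, computed from the authors' deposited tables. Activity-induced effectors had a lower response for 16 of 28 members and a higher one for 4 (17 and 4 adjusted over the list alone), with Arc at -1.57 ± 0.35 and Pim1 at -1.74 ± 0.24 computed from the authors' deposited tables. In contrast, dentate granule neuron markers had a higher response for 11 of 16 members and a lower one for 0 (12 and 0 adjusted over the list alone), a median difference of 0.70 computed from the authors' deposited tables.

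Immediate early transcription factors had a lower response for 7 of 23 members and a higher one for 3 (7 and 3 adjusted over the list alone), computed from the authors' deposited tables. Besides Fos and Atf3, the lower ones were Fosb (-0.74), Fosl2 (-0.79), Egr1 (-0.80), Egr2 (-0.97) and Ier2 (-0.69), and the higher ones Klf2 (0.96), Klf4 (1.63) and Maff (0.74), computed from the authors' deposited tables. The differences of Egr3 (-0.26 ± 0.14), Nr4a1 (-0.41 ± 0.31) and Npas4 (-0.63 ± 0.34), computed from the authors' deposited tables, did not pass. Heat shock and unfolded protein response genes had a lower response for 15 of 20 members (17 adjusted over the list alone), computed from the authors' deposited tables. So did reactive astrocyte markers for 9 of 12 (10 adjusted over the list alone) and microglial markers for 9 of 14 (11, with 1 higher, adjusted over the list alone), computed from the authors' deposited tables. MAP kinase feedback genes followed with 5 of 14 lower (5 adjusted over the list alone) and endothelial and mural markers with 4 of 14 (6 adjusted over the list alone), computed from the authors' deposited tables. Synaptic adhesion and scaffold genes had a higher response for 20 of 31 members and a lower one for 1 (22 and 1 adjusted over the list alone), computed from the authors' deposited tables. Potassium channel genes had a higher response for 13 of 26 and a lower one for 2 (14 and 2 adjusted over the list alone) and glutamate receptor genes a higher one for 9 of 22 (11 adjusted over the list alone), computed from the authors' deposited tables.

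By smallest adjusted p, the genes with a lower response were, besides Atf3 and Ddit3, Stk40 (-1.27), the lysosomal enzyme gene Gla (-1.48), Sesn2 (-1.80), Atf4 (-0.95), Plk3 (-1.64), the heme oxygenase gene Hmox1 (-1.93), Rgag4 (-1.33) and Gadd45b (-1.33), computed from the authors' deposited tables. Those with a higher response were Lrrc10b (1.94), Sipa1l3 (1.17), Fkbp5, a glucocorticoid-induced gene (1.35), Mdga1 (1.19), the calcium channel subunit gene Orai2 (1.19), Zbtb16 (1.18), Arhgap39 (1.10), Sh3bp5 (1.27), Islr2 (1.19) and Creg2 (0.97), computed from the authors' deposited tables. In total 3426 of 14386 genes differed, 1850 with a higher and 1576 with a lower response with shRNA-cFos, computed from the authors' deposited tables. With a fold minimum of 1.5 the balance turned, to 43.6% higher of 1708 genes, computed from the authors' deposited tables. Estimated E0 levels, set across tables that were normalized separately, stood higher with shRNA-cFos for interferon genes (median log2 ratio 1.57) and lower for granule neuron markers (-0.59), computed from the authors' deposited tables without a test. At E1 the granule neuron ratio was 0.06 and the interferon ratio -1.03, computed in the same way from the authors' deposited tables. The E0 and E1 ratios were 2.13 and -0.98 for Atf3, 1.28 and -0.88 for Ddit3 and 0.91 and -0.29 for reactive astrocyte markers, the larger part lying at E0. For Arc they were 0.35 and -0.63, the larger part lying at E1, from the authors' deposited tables.

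The 2 E1 responses shared nearly all genes induced at least 4-fold with shRNA-Ctrl. Of the 64 genes at least 4-fold higher at E1 with shRNA-Ctrl, 63 also rose with shRNA-cFos and 41 differed in size, with medians of 2.66 and 2.21 from the authors' deposited tables. Of the 239 genes that rose 2 to 4-fold with shRNA-Ctrl, 123 rose and 41 fell with shRNA-cFos and 156 differed, from the authors' deposited tables. Among the 2266 genes that rose by under 2-fold with shRNA-Ctrl, 700 rose and 226 fell with shRNA-cFos in the authors' deposited tables. These classes were picked by their change with shRNA-Ctrl, which by itself favours a smaller change in the other arm. No classes picked by shRNA-cFos were examined, so the medians of 2.66 and 2.21 do not by themselves show a weaker induction. Across genes, which are not independent replicates, the Spearman correlation of the log2 fold changes was 0.183 over 14386 genes from the authors' deposited tables. Genes higher in both arms numbered 886 against 419 for independent lists, and genes lower in both 605 against 293, from the authors' deposited tables. Genes that rose with shRNA-Ctrl and fell with shRNA-cFos numbered 267 against 302 for independent lists, and the reverse 303 against 408, from the authors' deposited tables. The slope by total least squares over the 7044 genes called in either arm was 0.690, from the authors' deposited tables.

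**Figure D2:**
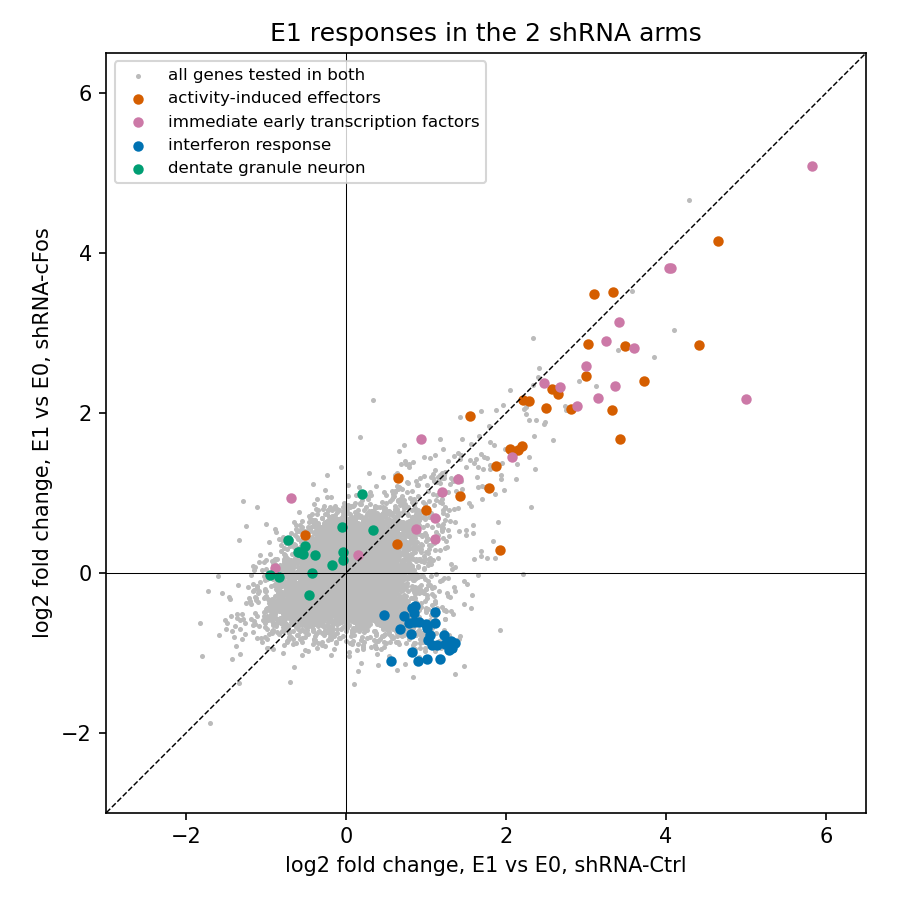
Log2 fold change at E1 with shRNA-cFos (vertical axis) against that with shRNA-Ctrl (horizontal axis) for the 14386 genes tested in both of the authors' deposited tables, with 4 gene lists in colour and the line of equal response dashed. Activity genes lie at the upper right (effector medians 2.39 and 2.04) and interferon response genes at the lower right (medians 1.01 and -0.78).

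The fourth comparison set c-Fos overexpression against EYFP in mice to which the labels assign neither E0 nor E1. The direction was read from Fos, which the table lists as higher, since the table header gives none. The genes that rose with the smallest adjusted p, Fos not among them, included Sprr1a, known from injured sensory neurons (6.20 ± 0.17), in the authors' deposited table. Others there were the enkephalin precursor gene Penk (3.44 ± 0.12), the sorting receptor gene Sorcs1 (3.56 ± 0.14) and the receptor tyrosine kinase gene Ret (3.56 ± 0.15). Several immediate early transcription factors fell: of 23 tested, 8 were lower and 4 higher in the authors' deposited table (8 and 4 adjusted over the list alone, median -0.21). The lower ones were Nr4a1 (-1.41 ± 0.15), Npas4 (-1.38 ± 0.19), Egr1 (-1.27 ± 0.13), Egr4 (-1.15), Nr4a2 (-1.07), Nr4a3 (-0.86), Junb (-0.82) and Fosb (-0.79), and the higher ones, besides Fos, Atf3 (1.52), Csrnp1 (0.60) and Fosl2 (0.35), in the authors' deposited table. Activity-induced effectors rose for 10 of 28 members and fell for 2 in the authors' deposited table (12 and 3 adjusted over the list alone), with a median of 0.21. Rgs4 (1.73 ± 0.09), Nptx2 (1.60 ± 0.20) and Pim1 (1.35 ± 0.18) were among the higher and Rasl11a (-0.97 ± 0.18) among the lower ones in the authors' deposited table.

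Reactive astrocyte markers rose for 10 of 11 members in the authors' deposited table, with a median of 0.82, or 1.35 with the prior removed (10 adjusted over the list alone), including the complement gene C3 (1.12 ± 0.20) and Gfap (0.86 ± 0.20). Microglial markers rose for 8 of 14 members in the authors' deposited table (11 adjusted over the list alone, median 0.43), as in Cd68 (0.91 ± 0.15). Interferon response genes rose for 11 of 28 members in the authors' deposited table (11 adjusted over the list alone, median 0.37, or 0.68 with the prior removed). The authors' deposited table gives no p, as DESeq2 does for a count far from the others, for 9 genes, of which 7 are interferon-induced. The oligodendrocyte median was -0.33, with 2 of 12 lower in the authors' deposited table (2 adjusted over the list alone). With the prior removed this median was -0.57, and the standard errors of the list were 4.07 times those of genes of like mean count, computed from the authors' deposited table. Endothelial and mural markers fell for 5 of 14 members in the authors' deposited table (6 adjusted over the list alone). Dentate granule neuron markers fell for 7 of 16 members and rose for 1 in the authors' deposited table (9 and 2 adjusted over the list alone, median -0.32), with Sema5b at -0.97 ± 0.14. Glutamate receptor genes fell for 9 of 22 members and rose for 1 in the authors' deposited table (10 and 1 adjusted over the list alone). In the authors' deposited table potassium channel genes fell for 10 of 26 with 2 higher (12 and 5 adjusted over the list alone) and calcium channel and signalling genes for 11 of 28 with 3 higher (12 and 3 adjusted over the list alone). Neuropeptide and secretory genes went both ways, 7 of 20 higher and 5 lower in the authors' deposited table (8 and 5 adjusted over the list alone), with Npy at 1.18 ± 0.11 and Cck at -0.88 ± 0.10. MAP kinase feedback genes fell for 4 of 14 members and rose for 1 in the authors' deposited table (6 and 1 adjusted over the list alone), with Dusp6 at -0.97 ± 0.13.

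The remaining genes with the smallest adjusted p that rose were, in the authors' deposited table, Ecel1 (2.95), the antioxidant gene Srxn1 (2.15), Igfbp6 (2.28), Card14 (3.09) and the synaptotagmin gene Syt6 (2.08). Those that fell were, in the authors' deposited table, Cyp26b1, which encodes a retinoic acid hydroxylase (-1.86), the IP3 receptor gene Itpr1 (-0.78), Enc1 (-0.69), the CaMKII inhibitor gene Camk2n1 (-0.86), Nwd2 (-0.99), Kalrn (-0.67) and Kctd4 (-0.78). In all, 2052 of 15827 tested genes passed an adjusted p of 0.05 in the authors' deposited table, 1124 higher and 928 lower. Large changes were nearly all increases, 137 higher and 13 lower by at least 2-fold in the authors' deposited table. The count was 1366 at an adjusted p of 0.01 and 615 with a fold minimum of 1.5, of which 76.7% were higher, from the authors' deposited table.

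**Figure D3:**
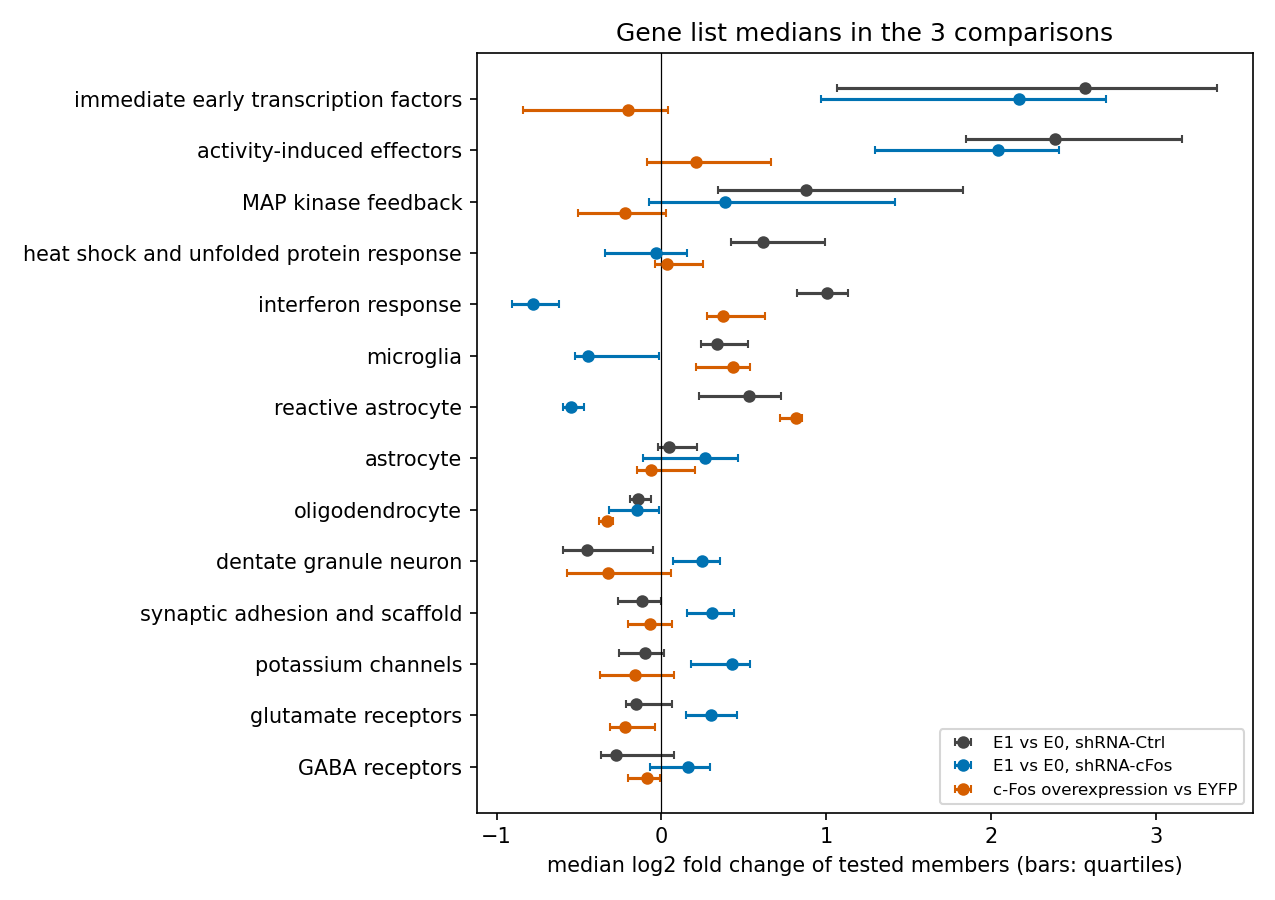
Median log2 fold change (horizontal axis) of the tested members of 14 gene lists in the authors' 3 deposited tables, with bars from the lower to the upper quartile of members. The immediate early and effector lists lie above 0 at E1 in both shRNA arms (2.57 and 2.39, then 2.17 and 2.04) and nearer 0 with overexpression (-0.21 and 0.21), and the interferon response list changes side between shRNA-Ctrl (1.01) and shRNA-cFos (-0.78).

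The last comparison asked whether genes that followed activation also followed c-Fos overexpression, in tables that share no libraries. Genes higher with overexpression and higher at E1 with shRNA-Ctrl numbered 401 against 184 for independent lists (2-sided Fisher's exact test, p = 5.7e-61), and genes lower in both 315 against 151, from the authors' deposited tables. For shRNA-cFos the largest excess was in opposite directions: 365 genes rose at E1 and fell with overexpression against 150 for independent lists, from the authors' deposited tables (2-sided Fisher's exact test, p = 1.3e-69). A further 175 fell at E1 and rose with overexpression against 124, from the authors' deposited tables. Genes higher in both were also in excess, 209 against 173 (2-sided Fisher's exact test, p = 0.0021), and genes lower in both numbered 79 against 108, from the authors' deposited tables. The Spearman correlation across genes, which are not independent replicates, was 0.211 over 15514 genes with shRNA-Ctrl and -0.165 over 14343 genes with shRNA-cFos, from the authors' deposited tables. Fisher's test also takes genes as independent draws. Medians of the interferon, microglial and reactive astrocyte lists lay above 0 with shRNA-Ctrl (1.01, 0.34, 0.53) and overexpression (0.37, 0.43, 0.82). With shRNA-cFos they lay below 0 (-0.78, -0.45, -0.55). Granule neuron medians ran opposite (-0.45 with shRNA-Ctrl, -0.32 with overexpression and 0.24 with shRNA-cFos). Lists other than activation genes thus ran in the directions of the overlaps, whose makeup by list was not examined. Among genes also tested with shRNA-cFos, Fos left out, 394 were higher at E1 with shRNA-Ctrl and with overexpression. Of these, 372 lay outside the glial and interferon lists, which are short. Nptx2 and Atf3 rose in all 3 of the authors' deposited tables, whereas Egr1, Nr4a1 and Npas4 rose at E1 in both arms and fell with overexpression.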

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

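The tests on the neuronal share, the granule neurons, the Fos counts, the priors and the genes of opposite direction were chosen only after the results they bear on had been seen. All values in this part are computed from the authors' deposited tables. No split of the animals into other groups was tried, since the tables hold no values per library.

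The E1 response differed between the 2 hairpins, by the test of the difference itself, for 3426 genes and for Fos (-1.03). Among the genes with the smallest adjusted p the response was higher with shRNA-cFos for Lrrc10b (1.94), Sipa1l3 (1.17), Fkbp5 (1.35), Mdga1 (1.19), Orai2 (1.19), Zbtb16 (1.18), Arhgap39 (1.10), Sh3bp5 (1.27), Islr2 (1.19) and Creg2 (0.97). It was lower for Stk40 (-1.27), Ddit3 (-2.00), Gla (-1.48), Sesn2 (-1.80), Atf3 (-2.83), Atf4 (-0.95), Plk3 (-1.64), Hmox1 (-1.93), Rgag4 (-1.33) and Gadd45b (-1.33). Of the lists fixed in advance, 13 had a median difference in the outermost 0.5% of matched random lists on either side. The median was lower with shRNA-cFos for immediate early transcription factors (-0.34), activity-induced effectors (-0.48), MAP kinase feedback (-0.27), heat shock and unfolded protein response (-0.58), interferon response (-1.75), CA1 and CA3 pyramidal neuron (-0.29), reactive astrocyte (-1.07), microglia (-0.76) and endothelial and mural (-0.39). It was higher for glutamate receptors (0.32), potassium channels (0.33), synaptic adhesion and scaffold (0.39) and dentate granule neuron (0.70). In the CA1 and CA3 list the single calls went the other way, with 4 of 15 members higher and 1 lower.

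Of 29 interferon genes 29 rose at E1 with shRNA-Ctrl and 23 fell with shRNA-cFos, and of 14 microglial markers 10 rose with shRNA-Ctrl, while 8 fell and 1 rose with shRNA-cFos. A lower share of neurons alone would raise the markers of all other cell types alike. In shRNA-Ctrl the oligodendrocyte median lay below the microglial median by a log2 difference of -0.48 (bootstrap over genes, with no error between animals, 95% interval -0.69 to -0.32). Medians above 0 there were reactive astrocyte (0.53), blood and lymphocyte (0.45), oligodendrocyte precursor (0.19), endothelial and mural (0.16) and plain astrocyte (0.04). Choroid plexus and ependymal (-0.26) and granule neuron medians (-0.45) lay below 0. An equal rise of all other cell types is thus argued against, while an unequal change in the mix of cells stays open and untested. Animals that differ in inflammation within a group may contribute, as standard errors of interferon genes, with the prior removed, were 1.44 times those of genes of like mean count with shRNA-cFos and 3.14 times with shRNA-Ctrl, though not for these genes alone (oligodendrocyte 2.03 and 1.70, immediate early 1.35 and 1.51). A higher E0 level in the shRNA-cFos mice cannot be told apart from an effect at E1. Of 27 interferon genes with estimated levels, 27 stood higher at E0 and 27 lower at E1 with shRNA-cFos. The median log2 ratio at E0 was 1.57 (95% interval 1.26 to 1.80 from a bootstrap over genes alone, with no error between animals). At E1 it was -1.03, in an unshrunken response difference of -2.72. The levels were set across separately normalized tables, and the interval reached below the E0 ratio that the plan asked for. These values and the ratios of standard errors rest on the prior removal, which is uncertain for several interferon genes, and the interval does not include that. An effect of c-Fos on these genes stays open and untested, with 11 of 28 interferon genes higher after overexpression, where 7 of the 9 genes left without a p for an outlying count were also interferon-induced.

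The 2 arms differed in their E1 responses over many gene groups. With the prior removed 3366 genes differed. The removal scales each change and its standard error by the same factor, and the priors were close (standard deviations 0.59 and 0.53). The count could thus hardly change, so it cannot decide on different priors in the tables. A milder response alone in the shRNA-cFos mice keeps the sign of each change, so it would not give the 570 genes called in opposite directions in the 2 arms. Of these, 267 rose with shRNA-Ctrl and fell with shRNA-cFos and 303 did the reverse, fewer than the 302 and 408 of independent lists. The count cannot decide on a milder response joined to an E0 difference between the arms. For the other genes a milder response cannot be told apart from other causes: the slope of shRNA-cFos on shRNA-Ctrl changes was 0.307 over 5004 genes outside the activity lists and 0.785 over 62 within them, and errors in small changes also lower a slope. Estimated level differences between the arms at E0 and at E1, from separately normalized tables, had a Spearman correlation of -0.259 over 12308 genes outside the interferon and glial lists, which are not independent. An exchange of E0 with E1 within an arm is argued against by the immediate early transcription factors. Of these, 20 of 24 rose and 2 fell with shRNA-Ctrl, and 20 of 23 rose and 0 fell with shRNA-cFos. A shared batch, which no label gives, groups exchanged between the arms, an E0 difference between the arms and an effect of the hairpin on the response stay open and untested.

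Of 23 immediate early transcription factors tested with c-Fos overexpression, 8 fell and 4 rose. Counts taken up by the overexpressed transcript are argued against by its share, as Fos held 0.173% of the mean normalized counts. Fewer granule neurons cannot be told apart from other causes: the granule marker median minus the median of the 22 tested members other than Fos was -0.0937 (bootstrap over genes, 95% interval -0.36 to 0.60). That median spans members that fell, rose or did not pass, so it cannot decide the question for the 8 that fell. Repression of some of these genes by added c-Fos, and differences in handling or activity between the groups, stay open and untested.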

How the results depend on the processing

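Removal of the prior was chosen after seeing the data, and the other settings were planned. No paired analysis was possible because the tables hold the authors' comparisons and no values per library, and for the same reason leaving out replicates, other pseudocounts, rescaling, refits with edgeR, limma or DESeq2, another sharing of the spread and set tests were not run. From the authors' deposited tables, an adjusted p of 0.01 left 2622 genes for shRNA-cFos, 1366 for overexpression and 2202 for the difference of responses. A fold minimum of 1.5 left 1660 genes for shRNA-Ctrl, 1077 for shRNA-cFos, 615 for overexpression and 1708 for the difference, and on unshrunken changes 1826, 1328 and 841 for the first 3, all fewer by construction. That minimum moved the share of higher genes from 51.0% to 61.4% for shRNA-Ctrl, from 58.2% to 53.9% for shRNA-cFos (50.2% unshrunken, and 64.7% at an adjusted p of 0.01), from 54.8% to 76.7% for overexpression and from 54.0% to 43.6% for the difference. In the other 33 alternative values of the main results, counts stayed within 1.5 times, correlations within 0.1, and the Fos changes past the threshold. With the prior removed 3366 genes differed between the arms, 3346 of them among the 3426. The 80 named results for single genes all stayed past the threshold with the same sign, which was largely fixed in advance. They had been picked by the smallest adjusted p, which the mean count filters hardly change. Within a single comparison, prior removal, for Fos too, cannot change a sign, and the authors' adjusted p was kept. Only the differences of responses were tested again after it. Of the alternative values of list medians 130 moved by less than the spread of their members and 8 by more, all 8 larger in size with the prior removed, such as interferon response in shRNA-Ctrl (1.55) and, with overexpression, reactive astrocyte (1.35) and oligodendrocyte (-0.57). The 2 medians that changed sign, neurogenic lineage and interneuron in the difference, lay next to 0. Depth per library is unknown. In the self-test, with 200 of 14386 genes changed, differences of 0.5 were recovered for 32% of genes. With 3426 genes called in the data the adjusted threshold is looser, so the share recovered there is not known, and small differences may be missed.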

Other observations

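The test of c-Fos-dependent induction was planned before its result was seen, and that of its 2-fold subset was added afterwards. The 4 added gene lists were chosen after the leading genes had been seen, and they share members with the lists fixed in advance. Per1, Sgk1 and Errfi1 (glucocorticoid) and Btg2 and Plk3 (p53) are also activity-induced effectors. Ddit3, Atf4 and Trib3 (integrated stress response) are also in the heat shock and unfolded protein list. Such members were not left out of the counts below. Targets of p53, a list added afterwards, rose at E1 with shRNA-Ctrl for 19 of 24 members and fell for 2 in the authors' deposited table (19 and 2 adjusted over the list alone), with Pmaip1 at 2.21 and Gtse1 at 1.92. With shRNA-cFos 3 rose and 9 fell in the authors' deposited table (4 and 9 adjusted over the list alone), and the response was lower for 18 of 24 (19 adjusted over the list alone, median difference -1.22). Integrated stress response genes, also added, rose for 13 of 21 and fell for 2 with shRNA-Ctrl, and rose for 2 and fell for 10 with shRNA-cFos, in the authors' deposited tables (16, 2, 3 and 11 adjusted over the list alone). Their response was lower for 12 of 21 and higher for 1, computed from the authors' deposited tables (13 and 1 adjusted over the list alone), and with overexpression 3 rose and 3 fell (4 and 3 adjusted over the list alone). Glucocorticoid-responsive genes, added as well, rose for 9 of 20 with shRNA-Ctrl, 16 with shRNA-cFos and 8 with overexpression in the authors' deposited tables (9, 16 and 10 adjusted over the list alone). They fell for 2, 0 and 1 in the authors' deposited tables (2, 1 and 2 adjusted over the list alone), and the response was higher with shRNA-cFos for 8 and lower for 2 (9 and 4 adjusted over the list alone). The axon injury list, which holds Sprr1a and Ecel1 because they had been seen, rose for 12 of 19 with shRNA-Ctrl, 9 of 17 with shRNA-cFos and 8 of 20 with overexpression in the authors' deposited tables (12, 10 and 9 adjusted over the list alone). It fell for 1, 3 and 0 members in the authors' deposited tables (2, 3 and 0 adjusted over the list alone), and the response was higher with shRNA-cFos for 3 of 17 and lower for 4 (4 and 5 adjusted over the list alone). With overexpression 5 of the p53 targets rose and 2 fell in the authors' deposited table (5 and 3 adjusted over the list alone).

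Among lists fixed in advance, interneuron markers rose for 8 of 12 members with shRNA-Ctrl and 6 of 12 with shRNA-cFos in the authors' deposited tables (9 and 6 adjusted over the list alone), with medians of 0.32 and 0.37. With overexpression 1 rose and 1 fell in the authors' deposited table (2 and 1 adjusted over the list alone), with a median of -0.23. GABA receptor genes fell for 8 of 14 and rose for 1 with shRNA-Ctrl, and rose for 4 and fell for 2 with shRNA-cFos, in the authors' deposited tables (8, 1, 4 and 2 adjusted over the list alone). The neurogenic lineage list had 3 of 16 higher and 3 lower with shRNA-Ctrl, 5 of 15 and 5 with shRNA-cFos and 5 of 16 and 1 with overexpression in the authors' deposited tables (3, 3, 5, 5, 5 and 3 adjusted over the list alone). In it Sox11, a marker of immature neurons, rose in all 3 of the authors' deposited tables (1.22, 1.19 and 0.79), while Top2a, a gene of dividing cells, rose with shRNA-Ctrl (0.63) and overexpression (0.89) and fell with shRNA-cFos (-0.71). Plain astrocyte markers rose for 2 of 12 with shRNA-Ctrl in the authors' deposited table (1 adjusted over the list alone). CA1 and CA3 pyramidal markers had medians of 0.12 with shRNA-Ctrl, -0.03 with shRNA-cFos and -0.19 with overexpression, thalamic markers 0.04, 0.07 and -0.21, and choroid plexus and ependymal markers -0.26, -0.13 and 0.10, from the authors' deposited tables. Oligodendrocyte precursor markers had medians of 0.19, 0.05 and -0.06, endothelial and mural markers 0.16, -0.16 and -0.20, and blood and lymphocyte markers 0.45 (0.76 with the prior removed), -0.15 and 0.28, in the same order of the authors' deposited tables. Calcium channel and signalling genes rose for 3 of 28 and fell for 7 with shRNA-Ctrl, and rose for 14 and fell for 1 with shRNA-cFos, in the authors' deposited tables (3, 7, 14 and 1 adjusted over the list alone). Of 4 sex-linked transcripts tested 1 rose in each of the authors' deposited tables, Ddx3y at E1 with shRNA-Ctrl (0.76) and shRNA-cFos (0.35) and Eif2s3y with overexpression (0.63), while the mean level of Xist was too low to be tested. With overexpression, 9 genes have a fold change and no p, and 7 of them, Cxcl10, Cxcl9, Gbp10, Gbp2, Gbp6, Gm4951 and Igtp, are interferon-induced, a grouping made after the names were seen in the authors' deposited table.

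A hypothesis is that genes that follow added c-Fos depend on c-Fos for part of their E1 response. Of the 394 genes higher with overexpression and higher at E1 with shRNA-Ctrl, Fos left out, 88.3% had a difference below 0 with shRNA-cFos, whether or not it passed, against 82.2% of the 2162 other genes that rose with shRNA-Ctrl (2-sided Fisher's exact test, p = 0.00263, across genes that are not independent), computed from the authors' deposited tables. The difference itself passed as lower for 235 and 791 genes of these sets, and the median differences were -0.57 and -0.28, computed from the authors' deposited tables. Outside the glial and interferon lists and at a fold of at least 2 with shRNA-Ctrl, the shares were 93.1% of 58 genes and 84.7% of 222, a gap that did not pass (2-sided Fisher's exact test, p = 0.130), computed from the authors' deposited tables. High shares in both sets come in part from picking genes by their shRNA-Ctrl change, and E0 differences between the arms may add to the gap between 88.3% and 82.2%.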
